A study of Mus musculus with 6 samples.

How the data were processed

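Nuclei were taken from the kidney cortex of female C57bl/6 NCC-Cre-INTACT mice, in which Cre under the promoter of the NaCl cotransporter NCC (gene Slc12a3) tags the nuclei of distal convoluted tubule (DCT) cells with a fluorescent protein. There were 6 libraries, 3 titled NK and 3 titled KD. Neither abbreviation is spelled out in the labels, and the treatment label reads control potassium diet for all 6, KD included. The descriptions list the 3 NK libraries alone among the sources of the control DCT, DCT1 and DCT2 objects, so the NK libraries were taken as the controls. The labels' ages were 23, 14 and 12 weeks for NK replicates 1, 2 and 3, and 23, 14 and 13 weeks for KD replicates 1, 2 and 3. Nothing beyond these labels states that the replicates are separate animals. The p-values of single genes and of shares therefore measure the spread between these samples. These are all 6 for KD against NK, and the 3 NK samples for the subtypes. Per the labels' protocols, 100000 nuclei per sample were sorted on green fluorescence and a red DNA stain, with low trigger pulse width to keep singlets. The series text instead speaks of the presence or absence of mCherry signal.

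The files hold UMI counts per gene and nucleus, as the deposited Cell Ranger matrices of 32285 genes. Per the submitters' processing notes, the authors demultiplexed with bcl2fastq, whose version is not given, and made the counts with Cell Ranger 6.1.2 against mm10, then analysed them in Seurat 4.2.0. The deposited matrices carry no cluster names, so every class of nuclei here was rebuilt and a difference from the authors' classes can come from that. Neither the strand setting of the counting nor the use of intron reads is stated. For that reason it is not known how well reads of overlapping or antisense gene pairs, such as Xist and Tsix, were kept apart. Reads shared between near-identical gene copies are uncertain too. Gene positions were taken from the GENCODE annotation of GRCm38, the assembly that mm10 also names.

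Nuclei with fewer than 500 detected genes or with over 5% mitochondrial UMIs were left out, which kept 74797 of 75373 barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0 nuclei, so the highest scores were left out at a rate of 0.8% per 1000 nuclei, between 8.16% and 11.2% of a library, and 67129 nuclei remained. Counts were scaled to 10000 per nucleus and logged, 2000 variable genes were chosen within libraries and scaled within each library, and nuclei were joined by 20 neighbours over 30 principal components. Leiden clustering at resolution 1 gave 23 clusters, named with the suffix "-like" from markers fixed beforehand, of which at least 3 had to be raised. Nuclei of a cycling cluster were placed by a vote of their neighbours after 852 genes raised in that cluster were left out. The 8 clusters named DCT-like, numbers 3 to 9 and 12, were clustered again at resolution 0.6 into 8 sub-clusters, each named DCT1-like or DCT2-like by the higher mean of the fixed markers. Clusters with over 50% predicted doublets and sub-clusters led by proximal tubule genes stayed unnamed, a limit set after the data were seen. Unnamed clusters held 1.81% ± 1.01 of NK nuclei and 1.75% ± 0.812 of KD nuclei (SD, n = 3 each), and unnamed sub-clusters held 122 nuclei. Some DCT-like clusters were led by stress or p53-related genes: cluster 8 by Ier3 and Mt1, cluster 9 by Trp53cor1, Pvt1 and Mgmt, and DCT1-like sub-cluster 5 by Pvt1, Cdkn1a, Trp53cor1 and Mgmt. In all, 49565 DCT-like nuclei were used, 36436 DCT1-like, 12789 DCT2-like and 340 proliferating-like.

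For each comparison the counts were summed per library and class, and the sums were tested across libraries, since nuclei are not replicates. Levels are given as CPM, the summed counts scaled to the total of their library and class, with that total adjusted by TMM. Single-library levels of Dusp1, Zbtb16, Fkbp5, Sgk1, Ankrd33b and the sex-linked genes were scaled to the plain totals. Tests were run with edgeR 4.0.16 by its quasi-likelihood method, with TMM scaling, the default filter on low counts and Benjamini-Hochberg adjustment at 0.05. For DCT1-like against DCT2-like nuclei of the NK libraries the library was a block. Genes were there divided at random into 2 sets, and each gene was tested between classes clustered without its own set, so that no tested gene helped to define the classes; the subtype markers were not tested. Whether the KD difference depends on the subtype was tested as an interaction with the library as a block. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Shares of nuclei were compared by 2-sided exact permutation tests of the 6 libraries, which cannot give a p under 0.1, and carry 95% Wilson intervals that cover counting error only. A nucleus was counted as cycling when it held UMIs of at least 3 of the 26 genes of the cell cycle list. For this share nuclei were also thinned to 1500 UMIs each.

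The design, the 12 marker lists, the 16 tested lists and the rule for the genes named were fixed before the data were examined. The tested lists were the NCC and WNK-SPAK pathway, basolateral potassium and chloride exit with the sodium pump, magnesium handling, calcium handling, and aldosterone response with the epithelial sodium channel (ENaC). Further lists were the circadian clock, oxidative phosphorylation, cell cycle, immediate early genes, tubule injury, interferon response, cholesterol synthesis, glycolysis, fatty acid oxidation, cytosolic ribosomal proteins, and heat shock with the unfolded protein response. The rule named up to 5 genes per direction with the largest change among those past the threshold, with at least 20 CPM and the same direction in every replicate, leaving out predicted genes. It also named up to 3 members per list with the smallest p, and Slc12a3, Trpm6, Wnk4, Sgk1 and Scnn1b throughout.

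The tests were tried on simulated counts with 200 changed genes. Of genes changed 2-fold, edgeR recovered 32.0% for KD against NK in all DCT-like nuclei, 37.4% in DCT1-like, 51.0% in DCT2-like, 84.8% for DCT1-like against DCT2-like, and 67.0% for the interaction. At 4-fold it recovered 83.5%, 89.8%, 94.8%, 100% and 92.0%, and false calls were 8.20%, 4.58%, 7.24%, 10% and 10.7% of the calls. With the gene sets of the subtype test simulated without any change, 28 of 11469 genes were called when both sets were normalised together and 1 of 11495 when each was normalised alone. The main fit normalised both sets together. Classes made from the tested genes themselves gave 3 calls of 11459. The simulation therefore cannot show that dividing the genes lowers false calls. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a block for the replicate number, predicted doublets kept, stricter filters on nuclei (1000 genes, 1% mitochondrial), clustering per library or at doubled resolution, and each library left out in turn. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3, with the seed 1 throughout.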

Results

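Single-nucleus RNA was counted in 6 libraries of sorted kidney cortex nuclei, 3 of the NK group, taken as controls, and 3 of the KD group. The files held 10189, 14003 and 13346 barcodes for NK replicates 1, 2 and 3, and 10926, 13299 and 13610 for KD replicates 1, 2 and 3. Total UMI counts were 43503474, 64011482 and 71071230 in the NK libraries and 39669312, 64676943 and 81655550 in the KD libraries. Median UMIs per nucleus ran from 3012 in KD replicate 1 to 4801 in KD replicate 3. The median mitochondrial share was 0.333% in NK replicate 1 and 0.596% in KD replicate 1, against 0.0484% to 0.109% in the other 4 libraries.

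DCT-like nuclei made up 70.3% ± 13.1 of the NK nuclei and 77.7% ± 7.11 of the KD nuclei (SD, n = 3 each), a share that the fluorescence gate can set. The difference of 7.34 points lay below the NK SD and just above the KD SD. A 2-sided exact permutation test gave p = 0.5, where the smallest possible p is 0.1. Proximal tubule-like nuclei were the next class, with 15.0% ± 8.75 of NK and 10.4% ± 4.69 of KD nuclei. The pooled DCT-like nuclei of the groups drew on different clusters, and NK replicate 3 stood apart from the other libraries in these. Cluster 3 held 21.7% of the NK and 1.15% of the KD DCT-like nuclei, and 4905 of its 5438 nuclei came from NK replicate 3. Clusters 5, 7 and 12 held 16.3%, 15.0% and 15.5% of the NK and 23.1%, 24.7% and 18.0% of the KD DCT-like nuclei. With predicted doublets counted, NK replicate 3 had 203 nuclei in cluster 5, against 1264 to 2699 in the other libraries. In cluster 7 it had 225, against 1239 to 2613.

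The DCT1-like and DCT2-like nuclei of the NK libraries were compared to show how the early and the late part of the convoluted tubule differ in control kidneys. DCT2-like nuclei carried far more RNA of the epithelial sodium channel, which takes up sodium under aldosterone: its subunit Scnn1g stood at 261 ± 53.1 CPM in DCT2-like and 4.66 ± 2.43 in DCT1-like nuclei (SD, n = 3). Ryr2, a calcium release channel, stood at 204 ± 5.22 in DCT2-like and 10.2 ± 1.11 in DCT1-like nuclei. Slc12a3, the thiazide-sensitive cotransporter NCC that defines the segment, was higher in DCT1-like nuclei, at 17460 ± 750.3 against 11000 ± 937 CPM. Adamtsl3 was the gene named with the largest rise in DCT1-like nuclei, at 64.5 ± 33.7 against 1.11 ± 0.264. In mm10, Slc12a3 (ENSMUSG00000031766) lies on chromosome 8 from 94329201 to 94366214, Scnn1g (ENSMUSG00000000216) on chromosome 7 from 121734479 to 121768475, and Adamtsl3 (ENSMUSG00000070469) on chromosome 7 from 82335694 to 82614450.

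In all, 4403 of 14926 genes differed between the subtypes with edgeR, 2288 higher and 2115 lower in DCT1-like nuclei. The named genes higher in DCT1-like nuclei were Adamtsl3 (log2 5.76 ± 0.16 SE, adjusted p = 2.7e-10), Frmd4a (5.38 ± 0.24), Dusp15 (5.31 ± 0.13), Bmp6 (4.94 ± 0.32) and Fam124a (4.91 ± 0.14). Those lower were Scnn1g (log2 −5.90 ± 0.14 SE, adjusted p = 2.3e-08), Olfm1 (−5.73 ± 0.20), Arhgap8 (−5.69 ± 0.15), Gata2 (−5.68 ± 0.19) and Wscd2 (−5.33 ± 0.22). Slc12a3 was higher in DCT1-like nuclei by log2 0.67 ± 0.08 (adjusted p = 5.5e-05), the magnesium channel gene Trpm6 by 0.66 ± 0.07 (1.1e-05) and the kinase gene Wnk4 by 0.51 ± 0.06 (2.3e-05). Sgk1, a kinase induced by aldosterone, was lower in DCT1-like nuclei, at log2 −1.48 ± 0.11 (adjusted p = 7.6e-07), and Scnn1b at −3.67 ± 0.06 (1.2e-11). DESeq2 called 2637 genes, 2568 of them among edgeR's. In the KD libraries 3970 genes differed, and 2947 of the 14655 genes tested in both groups were called in both, 2942 of these in the same direction.

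Genes of the aldosterone response, ENaC and potassium secretion and of calcium handling were lower in DCT1-like nuclei. Of 10 calcium handling genes tested, 6 were lower and 2 higher (median log2 −1.64, camera adjusted p = 2.3e-04), among them Ryr2 (−4.33 ± 0.07), the plasma membrane calcium pump gene Atp2b4 (−1.87 ± 0.06) and the vitamin D receptor gene Vdr (−1.75 ± 0.06). Of 12 aldosterone and ENaC genes, 7 were lower and 2 higher (median −0.36, adjusted p = 0.047), among them Hsd11b2 (−2.67 ± 0.11), whose enzyme shields the mineralocorticoid receptor from glucocorticoids. That last call was lost without NK replicate 3 (adjusted p = 0.0689). Cholesterol synthesis genes were higher in DCT1-like nuclei, 14 of 15 over all genes and 15 adjusted over the list alone (median 1.24, adjusted p = 3.9e-10), with Msmo1 at 2.02 ± 0.14 and Fdft1 at 1.24 ± 0.09. Oxidative phosphorylation genes were higher too, 22 of 36 over all genes and 24 adjusted over the list alone (median 0.24, adjusted p = 1.2e-07), with Atp5g3 at 0.49 and Cox5b at 0.51. Of 10 immediate early genes 4 were higher, 5 adjusted over the list alone (median 0.96, adjusted p = 1.8e-04), with Dusp1 at 1.77 and Klf6 at 1.01. These 5 calls were lost when the correlation was estimated, with adjusted p = 0.396 for each with an estimated correlation. With fry the same lists gave adjusted p from 0.0022 to 0.048.

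At the preset correlation camera did not call the other 11 lists between the subtypes, and the adjusted p below are its own. Among these lists fry called magnesium handling upward in DCT1-like nuclei (adjusted p = 0.0145). It also called the NCC and WNK-SPAK pathway, interferon and fatty acid oxidation upward and injury downward, each at adjusted p = 0.048. Of 13 genes of the NCC and WNK-SPAK pathway 6 were higher in DCT1-like nuclei and 3 lower (adjusted p = 0.518), with the kinase gene Stk39 at log2 0.71 and Ppp1r1a at 0.74. Of 11 magnesium handling genes 4 were higher and 3 lower (adjusted p = 0.175), with Umod at 2.90 ± 0.11, Trpm7 at 2.33 ± 0.07 and Egfr at 1.32 ± 0.07. Of 10 genes of basolateral ion exit 3 were higher and 3 lower, such as Kcnj16 at −0.62 (adjusted p = 0.63). Of 15 clock genes 7 were higher, such as Cry1 at 1.19, and 3 lower, such as Arntl at −1.22 (adjusted p = 0.074). Of 15 fatty acid oxidation genes 4 were higher, such as Ppara at 1.19 and Pdk4 at 1.17, and 1 lower (adjusted p = 0.0906). Interferon genes were higher in 5 of 14 cases (adjusted p = 0.0555), glycolysis genes in 5 of 13 with 2 lower (0.081), and ribosomal protein genes in 2 of 26 (0.232). Heat shock genes were higher in 3 of 13 cases with 2 lower (adjusted p = 0.23), injury genes in 2 of 8 with 4 lower (0.454), and cell cycle genes in 2 of 13 (0.81). The median, mean and test of the cell cycle and injury lists differed in sign. The 9 marker lists tested here gave camera adjusted p from 0.0801 to 0.842.

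**Figure D1:**
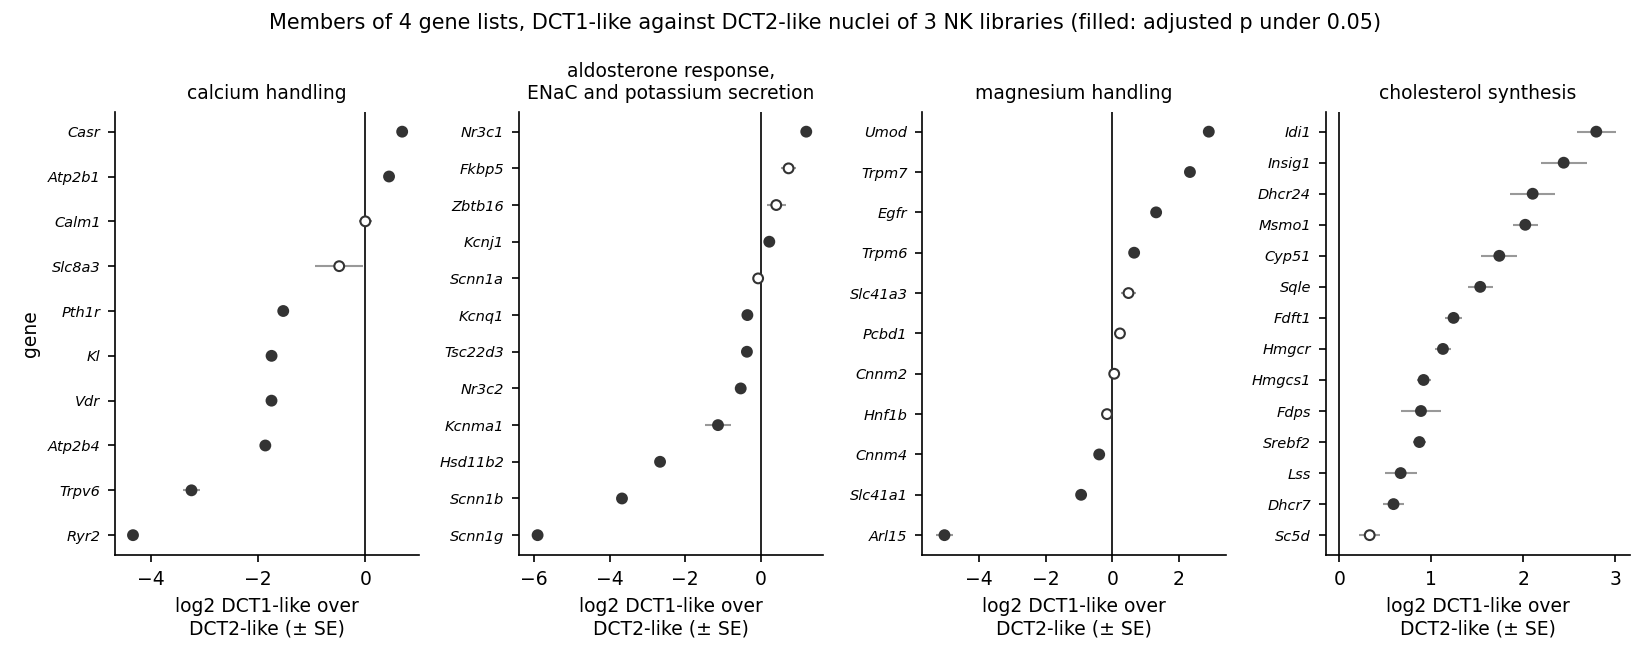
Log2 difference (DCT1-like over DCT2-like, NK libraries, n = 3) of the members of 4 gene lists, 1 point per gene with its SE, filled where the adjusted p is under 0.05. Scnn1g at −5.90, Scnn1b at −3.67 and Ryr2 at −4.33 stand lowest in their lists, and 13 of the 14 cholesterol synthesis genes drawn are filled, all of them above 0.

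KD was compared with NK to show what sets the KD samples apart from the controls. In all DCT-like nuclei the cell cycle genes stood higher in KD: Tpx2, a spindle gene, at 3.95 ± 0.636 against 0.867 ± 0.399 CPM (SD, n = 3 each). These sums include the proliferating-like sub-cluster, on average 0.191% of NK and 1.17% of KD DCT-like nuclei. The rise therefore need not extend to the other DCT-like nuclei. Cholesterol synthesis genes stood lower, with the epoxidase gene Sqle at 5.62 ± 1.70 in KD and 12.9 ± 0.469 in NK. Pdk4, whose kinase slows the use of glucose as a fuel, stood at 53.3 ± 28.3 in KD and 14.6 ± 6.27 in NK. The level of Slc12a3 was 15820 ± 2341 in KD and 15810 ± 625 in NK. No single gene passed the edgeR threshold over all genes in this comparison.

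All 26 cell cycle genes had positive log2 values, and 22 rose when adjusted over the list alone (median 1.57, camera adjusted p = 2.1e-46), with Tpx2 at 2.22 ± 0.38 SE, Kif20b at 2.04 ± 0.34 and Knl1 at 1.60 ± 0.29. All 15 cholesterol synthesis genes had negative values, and 3 fell when adjusted over the list alone (median −0.49, adjusted p = 2.0e-12), among them Sqle at −1.20 ± 0.24 and Msmo1 at −0.88 ± 0.23. Both lists gave adjusted p = 0.067 with an estimated correlation, and 0.0376 with fry. Fatty acid oxidation genes had positive values in 13 of 15 cases (median 0.20, adjusted p = 6.2e-05, adjusted p = 0.715 with an estimated correlation), and Pdk4 rose when adjusted over the list alone (1.87 ± 0.41), while Acadl was at 0.62 ± 0.21 and Acaa2 at 0.54 ± 0.23. Immediate early genes had positive values in 13 of 16 cases (median 0.35, adjusted p = 0.0040), with Egr1 at 2.06 ± 1.08 and Jund at 0.52 ± 0.23. Oxidative phosphorylation genes had negative values in 35 of 36 cases (median −0.14, adjusted p = 9.0e-04), with Sdhb at −0.15 ± 0.14, and ribosomal protein genes in 19 of 26 (median −0.08, adjusted p = 0.038). These last 3 lists gave adjusted p = 0.994 with an estimated correlation, and held 0 members past the threshold of edgeR adjusted over the list alone.

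NK replicate 3 had the lowest levels of Dusp1, of the immediate early list, and of Zbtb16 and Fkbp5, of the aldosterone list, genes chosen after their values were seen. Its Dusp1 level was 5.09 CPM, against 16.1 and 18.8 in NK replicates 1 and 2 and 11.5 to 26.1 in KD. Zbtb16 stood at 16.2 in it, against 72.1 to 106 in the other 5 libraries, and Fkbp5 at 145 against 210 to 390. For Sgk1 NK replicate 2 stood highest, at 36.4, against 14.9 and 4.04 in the other NK libraries and 6.64 to 9.66 in KD. Without NK replicate 3 the adjusted p of the immediate early genes was 0.773, and without KD replicate 3 it was 0.643. The oxidative phosphorylation call was lost without NK replicate 1 (0.562), KD replicate 2 (0.489) or KD replicate 3 (0.218), and the ribosomal call without NK replicate 1 (0.938) or KD replicate 2 (0.558), while without KD replicate 3 it turned upward (0.218). The glycolysis list was called without KD replicate 1 (adjusted p = 0.039), calcium handling without KD replicate 2 (0.0428), and the NCC and WNK-SPAK pathway, downward, without KD replicate 3 (0.0015).

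The other 10 lists gave adjusted p from 0.462 to 0.996, and median, mean and test differed in sign for the NCC and WNK-SPAK pathway, magnesium handling, clock, injury and heat shock lists. Arl15 of the magnesium list was at log2 0.56 ± 0.21. The fixed genes did not pass the threshold: Slc12a3 was at 0.00 ± 0.23, Trpm6 at −0.04 ± 0.27, Wnk4 at −0.45 ± 0.16, Sgk1 at −1.14 ± 0.63 and Scnn1b at −0.22 ± 0.13. Among the marker lists the proliferating markers were higher in KD, 10 of 10 when adjusted over the list alone (median 1.82, adjusted p = 8.3e-27, adjusted p = 0.113 with an estimated correlation), and all of these are also in the cell cycle list. The other 11 marker lists, proximal tubule, immune and stromal included, gave adjusted p from 0.60 to 0.808, with signs that differed for 4. Over all 16944 genes edgeR called 0, with 527 at an unadjusted p under 0.05 (384 higher, 143 lower) where 847.2 would pass by chance. DESeq2 called 99, 90 of them higher in KD, and 14 of the 99 were in the cell cycle list. Its calls outside that list, named here after their values were seen, included further genes of cell division or DNA replication. Among these were Ttk (DESeq2 log2 2.61), Cdca2 (2.19) and Dtl (2.83). The smallest adjusted p of DESeq2 outside the list belonged to 4930544F09Rik (−3.70), Xkr4 (1.94) and Kcnb2 (2.27). Others were Pak7 (−3.29), Lpo (2.95), Scpep1os (−1.97), Thbs1 (1.27), Txnip (0.79), Pdk4 (1.90), Sqle (−1.19) and Pctp (−0.85). The 3 KD and 3 NK libraries did not overlap for 1134 genes, 6.69% where chance gives 10%.

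**Figure D2:**
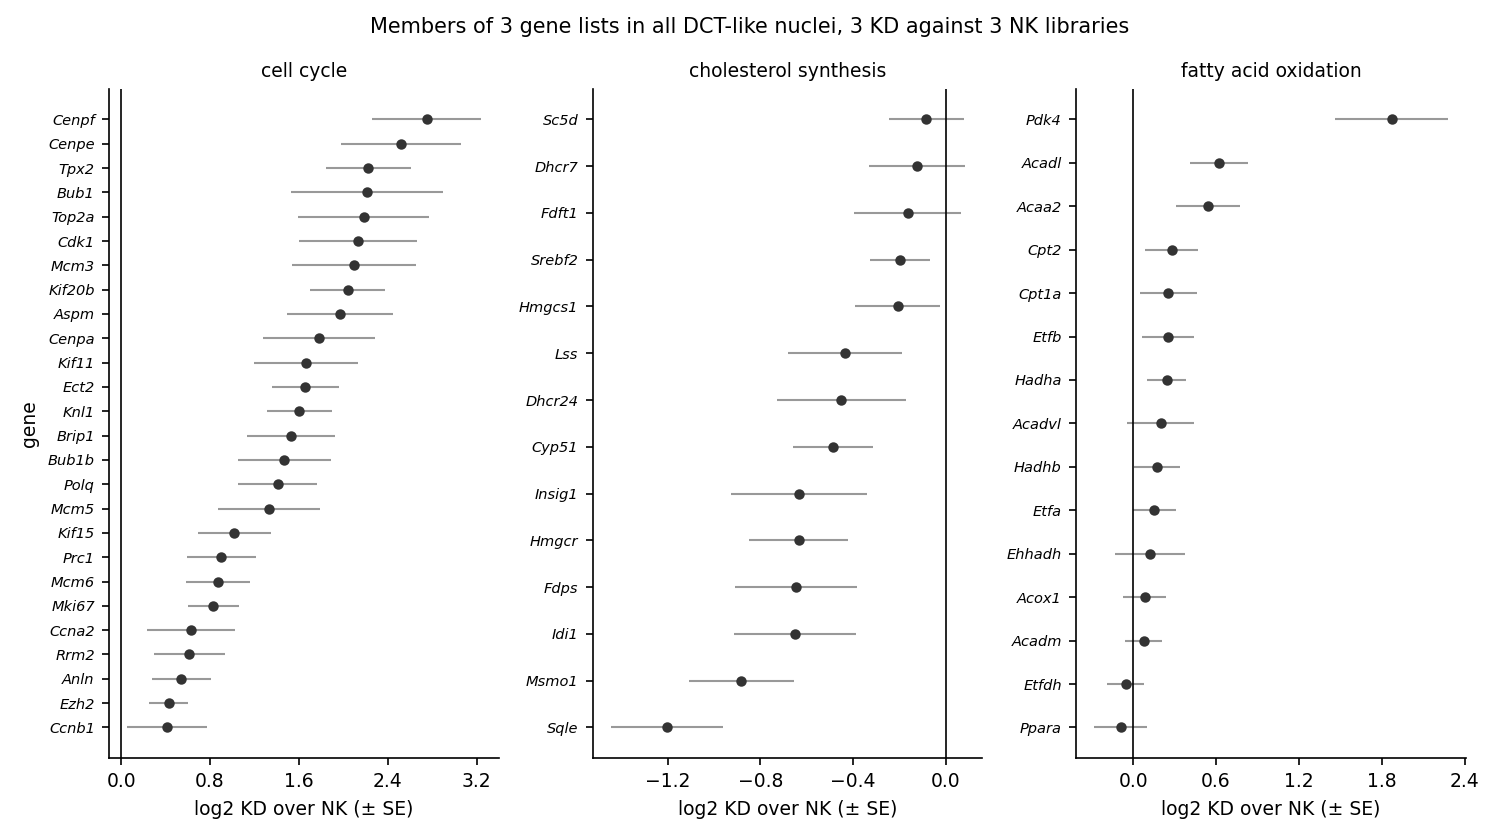
Log2 difference (KD over NK, all DCT-like nuclei, n = 3 libraries each) of the members of 3 gene lists, 1 point per gene with its SE. All 26 cell cycle genes lie above 0, all 14 cholesterol synthesis genes drawn lie below 0, and Pdk4 stands highest among the fatty acid oxidation genes at 1.87.

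Cycling DCT-like nuclei, with UMIs of at least 3 cell cycle genes, made up 0.308% ± 0.106 in NK and 1.30% ± 0.308 in KD (SD, n = 3 each), a 4.23-fold difference. NK replicate 1, the highest of its group, had 25 such nuclei of 6245 (0.400%, Wilson interval 0.271% to 0.590%). KD replicate 1, the lowest of its group, had 91 of 8323 (1.09%, interval 0.891% to 1.34%). The groups did not overlap (p = 0.1, 2-sided exact permutation test, the smallest possible p). With every nucleus thinned to 1500 UMIs, which left out 823 shallower NK and 1339 shallower KD nuclei, the shares were 0.166% ± 0.12 and 0.865% ± 0.16. Top2a, a topoisomerase of dividing cells, was detected in 0.200% of NK and 0.898% of KD nuclei (p = 0.1, exact permutation), and Mki67 in 2.79% and 3.30% (p = 0.7, exact permutation). Most cycling DCT-like nuclei of the KD libraries, 66 of 91, 65 of 106 and 107 of 140, were in the proliferating-like sub-cluster, which cell cycle genes set apart. In the DCT1-like nuclei that remained the cycling share was 0.167% ± 0.0756 in NK and 0.456% ± 0.0811 in KD, and in the DCT2-like nuclei 0.037% ± 0.064 and 0.196% ± 0.059. Outside the DCT, it was 0.952% ± 0.749 in NK and 1.52% ± 0.646 in KD among intercalated-like nuclei (p = 0.4, exact permutation) and 2.76% ± 1.2 and 5.02% ± 0.403 among proximal tubule-like nuclei (p = 0.1, exact permutation). Nuclei outside the DCT were not thinned. With at least 2 genes required the DCT-like shares were 2.03% and 3.59% (p = 0.2, exact permutation).

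**Figure D3:**
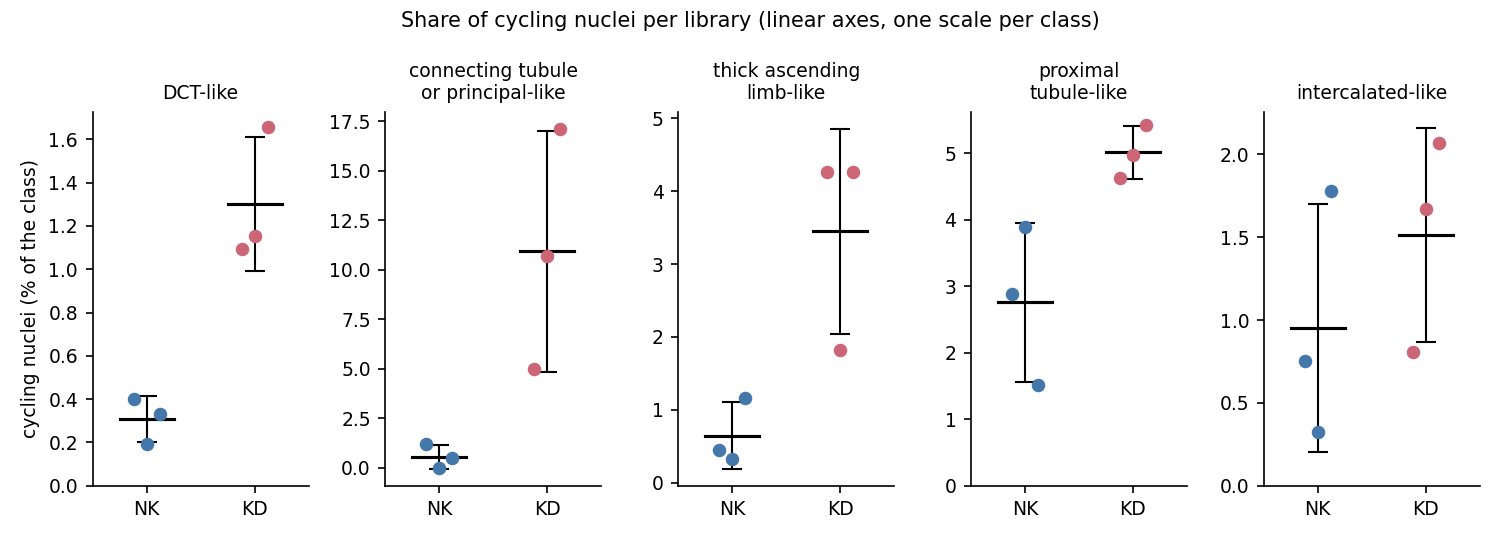
Percent of nuclei with UMIs of at least 3 cell cycle genes in 5 classes, 1 point per library, with mean and SD (n = 3 each; linear axes, 1 scale per class). The 3 KD libraries lie above the 3 NK libraries in DCT-like, connecting tubule or principal-like, thick ascending limb-like and proximal tubule-like nuclei, and overlap with them in intercalated-like nuclei.

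DCT2-like nuclei made up 23.7% ± 3.25 of the subtyped nuclei in NK and 27.8% ± 1.12 in KD (SD, n = 3 each), with NK from 20.0% to 25.9% and KD from 26.5% to 28.6% (p = 0.1, 2-sided exact permutation test, the smallest possible p). DCT1-like sub-cluster 0 held 36.9% of NK and 26.7% of KD DCT-like nuclei, DCT1-like sub-cluster 1 held 14.1% and 18.5%, and DCT2-like sub-cluster 2 held 18.5% and 23.1%. NK replicate 3 had the lowest DCT2-like share, and without it the difference was 2.21 points in place of 4.08. Clustered without 896 genes that leaned with the group, an alternative chosen after seeing the data, the difference was 4.03 points.

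Within DCT1-like nuclei, cholesterol synthesis genes were lower and fatty acid oxidation genes higher in KD. All 15 cholesterol genes had negative values and 3 fell when adjusted over the list alone (median −0.51, camera adjusted p = 1.6e-12, adjusted p = 0.223 with an estimated correlation), among them Sqle at log2 −1.13 and Msmo1 at −0.91. Fatty acid oxidation genes had positive values in 13 of 15 cases (adjusted p = 9.0e-06, adjusted p = 0.471 with an estimated correlation), and Pdk4 rose when adjusted over the list alone (1.89 ± 0.42 SE). Of 19 cell cycle genes tested 13 had positive values (adjusted p = 3.5e-04, adjusted p = 0.471 with an estimated correlation), and 1 rose when adjusted over the list alone, the kinetochore gene Cenpf, from 1.65 to 13.1 CPM (log2 3.05 ± 0.43). Oxidative phosphorylation genes were negative in 35 of 36 cases (median −0.16, adjusted p = 3.5e-04), ribosomal protein genes in 18 of 26 (0.0378), and immediate early genes positive in 13 of 16 (0.0122). These 3 gave adjusted p = 0.942 with an estimated correlation and, without NK replicate 3 and KD replicate 2, an alternative chosen after seeing the data, adjusted p = 0.230, 0.467 and 0.621.

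In DCT1-like nuclei the other 10 lists gave adjusted p from 0.382 to 0.876. Slc12a3 was at log2 0.01 ± 0.24, Trpm6 at −0.07 ± 0.27, Wnk4 at −0.39 ± 0.17, Sgk1 at −0.87 ± 0.61 and Scnn1b at −0.21 ± 0.20. Signs of median, mean and test differed for the NCC and WNK-SPAK, magnesium, calcium, clock and interferon lists. The proliferating markers gave adjusted p = 0.0038, and adjusted p = 0.755 with an estimated correlation. The other 10 marker lists gave 0.539 to 0.835. Of the 6 DCT2 markers 1 was higher and 1 lower in KD when adjusted over the list alone. Of 16031 genes edgeR called 0, with 416 at an unadjusted p under 0.05, and DESeq2 called 25, 18 higher and 7 lower. The DESeq2 calls included Egfem1, one of the fixed DCT2 markers, at log2 2.88 (adjusted p = 4.6e-05). The groups did not overlap for 967 genes, 6.03% where chance gives 10%.

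Within DCT2-like nuclei, immediate early genes were higher in KD. All 11 tested had positive values and 4 rose when adjusted over the list alone (median 0.49, camera adjusted p = 6.2e-07, adjusted p = 0.115 with an estimated correlation), among them Fos, from 0.452 to 2.35 CPM (log2 2.25 ± 0.52 SE), Jun (1.91 ± 0.42) and Dusp1 (1.38 ± 0.35). Fatty acid oxidation genes had positive values in 14 of 15 cases (adjusted p = 4.5e-05, adjusted p = 0.685 with an estimated correlation), and Pdk4 rose when adjusted over the list alone, from 7.14 ± 3.81 to 28.0 ± 9.03 CPM (1.99 ± 0.37). Egfr, the receptor through which EGF acts on magnesium uptake, rose when adjusted over the magnesium list alone, from 36.0 ± 2.04 to 58.6 ± 7.75 CPM (0.70 ± 0.15; list adjusted p = 0.14). Sqle fell when adjusted over the cholesterol list alone (−1.43 ± 0.32; list adjusted p = 0.457).

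In DCT2-like nuclei the 14 lists not called gave adjusted p from 0.140 to 0.878, with signs that differed for the NCC and WNK-SPAK and the injury lists. Of 11 cell cycle genes tested 5 had positive and 6 negative values (median −0.03, camera adjusted p = 0.769). Slc12a3 was at log2 0.13 ± 0.25, Trpm6 at 0.25 ± 0.27, Wnk4 at −0.50 ± 0.18, Sgk1 at −1.49 ± 0.68 and Scnn1b at −0.41 ± 0.16. DCT1 markers had positive values in 5 of 6 cases (median 0.72, adjusted p = 0.044, adjusted p = 0.95 with an estimated correlation), while the other 9 marker lists gave 0.687 to 0.947. Of 14105 genes edgeR called 0, with 393 at an unadjusted p under 0.05, and DESeq2 called 14, 11 higher and 3 lower. The groups did not overlap for 1013 genes, 7.18% where chance gives 10%.

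Whether KD differed from NK more in DCT1-like or in DCT2-like nuclei was tested as an interaction, and 4 of 15512 genes passed with edgeR, each with a more positive KD difference in DCT1-like nuclei. For Veph1, on chromosome 3 from 66053558 to 66296837, the extra difference was log2 1.17 ± 0.09 SE (adjusted p = 8.4e-05): it stood at 21.7 ± 2.14 in NK and 61.5 ± 19.5 CPM in KD in DCT1-like nuclei, and at 63.1 and 78.7 in DCT2-like nuclei. For Sult1c2, a sulfotransferase gene, it was 1.13 ± 0.16 (adjusted p = 0.0215), with KD differences of 0.06 ± 0.16 in DCT1-like and −1.07 ± 0.26 in DCT2-like nuclei. For Ankrd44 it was 0.98 ± 0.14 (adjusted p = 0.0215), with 0.52 ± 0.18 and −0.47 ± 0.18, and for the tetraspanin gene Tspan15 0.70 ± 0.10 (0.0215), with 0.19 ± 0.18 and −0.52 ± 0.19. Slc12a3 was at −0.11 ± 0.14, Trpm6 at −0.27 ± 0.16, Wnk4 at 0.12 ± 0.10, Sgk1 at 0.63 ± 0.16 and Scnn1b at 0.20 ± 0.10, none past the threshold. At an unadjusted p under 0.05 there were 1209 genes, and DESeq2 called 15, these 4 included. Veph1 passed without each library in turn (adjusted p from 2.7e-04 to 0.0031). Sult1c2, Ankrd44 and Tspan15 did not pass without NK replicate 2 (adjusted p = 0.0712, 0.0712 and 0.0548), NK replicate 3 (0.111, 0.111 and 0.125) or KD replicate 3 (0.149, 0.142 and 0.183), nor Ankrd44 and Tspan15 without NK replicate 1 (0.0632 and 0.0576). The count was 9 without NK replicate 1, 32 without KD replicate 1, 16 without KD replicate 2 and 2 without KD replicate 3. With a block for the replicate number, in a fit that drops the block for the library, none of the 4 genes passed. Their log2 values hardly moved in that fit, at 1.18 for Veph1, 1.12 for Sult1c2, 0.98 for Ankrd44 and 0.71 for Tspan15.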

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

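The depth test below was chosen after the cycling shares had been seen, as were the counts of cycling nuclei in classes outside the DCT. The KD minus NK difference was more positive in DCT1-like than in DCT2-like nuclei for 4 genes, by log2 1.17 for Veph1, 1.13 for Sult1c2, 0.98 for Ankrd44 and 0.70 for Tspan15, by an edgeR test of the interaction. All 6 libraries also held nuclei outside the DCT that no comparison was planned for, and in 3 of those classes the cycling share was higher in each KD library than in each NK library. It was 10.9% ± 6.08 in KD and 0.564% ± 0.603 in NK among connecting tubule or principal-like nuclei, 3.45% ± 1.41 and 0.644% ± 0.454 among thick ascending limb-like nuclei, and 5.02% ± 0.403 and 2.76% ± 1.2 among proximal tubule-like nuclei (SD, n = 3 each; p = 0.1 for each, exact permutation, the smallest possible p). Nuclei outside the DCT were not thinned, so a part of depth in these shares was not tested. The clusters of these classes also held Slc12a3 RNA, at 2.58 to 76.3 per 10000 UMIs. Whether their cycling nuclei carry RNA of DCT nuclei was not tested.

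The higher share of cycling DCT-like nuclei in KD was weighed against 3 technical explanations. A difference in depth would bring the groups together once each nucleus is thinned to the same UMIs, but the KD share was then 5.22-fold the NK share. Free RNA of dividing cells would spread the genes over nuclei independently, but at the lowest KD ratio the nuclei with at least 3 cell cycle genes were 10.7 times those that independence gives. A dividing nucleus of another class captured with a DCT nucleus would bring that class's RNA, which made up at most 0.801% of the RNA of cycling DCT-like nuclei in a KD library. The naming of classes had already sent nuclei with much RNA of another class elsewhere, so a low value was likely beforehand. It describes the nuclei counted and cannot by itself exclude joint capture. More DCT cells in division in KD may remain as a hypothesis, found and tested on the same data, with handling of the samples and what KD stands for untested.

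The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05, and each count of splits below includes the real one. Genes called numbered 0 for the real split and at most 2 for any other split in all DCT-like nuclei, 0 and 3 in DCT1-like nuclei, 0 and 1 in DCT2-like nuclei, and 4 and 9 for the interaction, and 10, 10, 10 and 2 splits gave at least as many as the real one. Lists called numbered 6 and at most 9 in all DCT-like nuclei (8 splits as many), 6 and 9 in DCT1-like nuclei (5 splits) and 2 and 6 in DCT2-like nuclei (10 splits). For the subtypes, swapping the classes within libraries gives 4 assignments, also too few: genes called numbered 4403 and at most 0 (1 assignment as many), and lists called 5 and 7 (2 assignments). For the other classes the real split and the highest other gave 64 and 4 genes in connecting tubule or principal-like nuclei (1 split as many), 0 and 0 in thick ascending limb-like, 0 and 14 in intercalated-like and 0 and 1 in proximal tubule-like nuclei (10 splits each). The split that sets NK replicates 1 and 2 with KD replicate 1 against the rest gave 2208 genes at an unadjusted p under 0.05 in all DCT-like nuclei, where the real split gave 527, which points to a structure of the samples apart from the groups.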

How the results depend on the processing

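The tests without NK replicate 3 and KD replicate 2 together, with each gene set normalised alone, without genes leaning with the group, those of lists without single libraries and those of classes outside the DCT were chosen after the results were seen. The 3 shares kept their direction in every alternative: the KD minus NK difference was 1.42 to 14.5 points for DCT-like nuclei over 10 alternatives, 1.96 to 5.16 for DCT2-like over 13 and 0.650 to 1.56 for cycling nuclei over 14. Without single libraries these were 1.72 (without NK replicate 3) to 14.5 (without NK replicate 2), 2.21 to 5.16 and 0.816 to 1.10; paired by replicate number, p = 0.5, 0.25 and 0.25 by exact sign flips, which cannot go under 0.25. Leaving out called genes from the clustering was void, since 0 were called. Of 1293 alternative values of 89 results for single genes, with a gene counted once per comparison, 1221 kept their direction and side of the threshold, 32 lost and 23 gained the threshold, and 17 turned sign, 0 of them of a called gene. DESeq2 gave 99 genes for KD against NK in all DCT-like, 25 in DCT1-like and 14 in DCT2-like nuclei, 2637 for the subtypes and 15 for the interaction, and 11 in thick ascending limb-like and 9 in proximal tubule-like nuclei. With no filter on low counts the counts were 2, 7 and 27 for all DCT-like, DCT1-like and DCT2-like nuclei, 258 for the interaction, 286 in connecting tubule or principal-like, 70 in thick ascending limb-like, 15 in intercalated-like and 2 in proximal tubule-like nuclei. Same-numbered libraries deviated with correlations of 0.474, 0.124 and −0.022, and 2 of 6 libraries correlated best with their own number, so the correlations give no sign that the numbers pair all libraries, although the labels give equal numbers like ages and replicate 1 of both groups had the highest mitochondrial shares. With the replicate block, 2 genes were called in all DCT-like, 4 in DCT1-like and 0 in DCT2-like nuclei, 0 for the interaction (where this fit drops the block for the library) and 76 in connecting tubule or principal-like nuclei, and 6 lists in all DCT-like nuclei; with no replicate block for the library, the subtypes differed in 1679 genes. Without single libraries the counts ran from 0 to 5 in all DCT-like nuclei (5 without NK replicate 1), 0 to 2 in DCT1-like (2 without NK replicate 1), 0 to 1 in DCT2-like (1 without NK replicate 1), 3182 to 3842 for the subtypes and 2 to 32 for the interaction. Outside the DCT they ran from 14 (without NK replicate 3) to 173 (without KD replicate 1) in connecting tubule or principal-like nuclei, with 16 without NK replicate 2, 21 without KD replicate 2 and 38 without KD replicate 3. They ran from 0 to 14 in thick ascending limb-like nuclei (14 without KD replicate 1, 1 without NK replicate 1), 0 to 1 in intercalated-like (1 without KD replicate 1) and 0 to 0 in proximal tubule-like nuclei. Without NK replicate 3 and KD replicate 2 together the interaction gave 16 genes. Each set of genes normalised alone gave 4424 subtype genes. Lists called fell to 0 in all 4 comparisons when the correlation was estimated; fry called 2 in all DCT-like, 0 in DCT1-like, 0 in DCT2-like nuclei and 10 for the subtypes. Without single libraries the lists numbered 4 to 7 in all DCT-like and in DCT1-like nuclei, 2 to 6 in DCT2-like (4 without NK replicate 1, KD replicate 1 or KD replicate 3, 6 without NK replicate 2) and 5 to 7 for the subtypes, and without NK replicate 3 and KD replicate 2 together 3 in all DCT-like and 3 in DCT1-like nuclei. Values of fixed genes that turned sign did so within these ranges without single libraries: in all DCT-like nuclei Slc12a3 log2 −0.12 (KD replicate 3) to 0.069 (KD replicate 2) and Trpm6 −0.31 (KD replicate 3) to 0.18 (NK replicate 3), and in DCT1-like nuclei Slc12a3 −0.10 (KD replicate 3) to 0.087 (KD replicate 1), Trpm6 −0.31 (KD replicate 3) to 0.15 (NK replicate 3) and Sgk1 −1.34 (NK replicate 3) to 0.18 (NK replicate 2). In DCT2-like nuclei these were −0.010 (KD replicate 3) to 0.32 (KD replicate 2) for Slc12a3 and −0.10 to 0.48 for Trpm6 (the same libraries), and for the interaction −0.27 (KD replicate 2) to 0.027 (KD replicate 1) for Slc12a3. With the replicate block Slc12a3 was at −0.0089 in all DCT-like nuclei, and without NK replicate 3 and KD replicate 2 together Trpm6 was at 0.30 in all DCT-like and 0.21 in DCT1-like nuclei. The cause of these shifts was not tested. Depth limits what the cycling shares of single libraries can show, since these rest on 20 to 140 nuclei.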

Other observations

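Each test in this part was chosen after its pattern was seen. In connecting tubule or principal-like nuclei 64 of 11459 genes passed with edgeR, all higher in KD, with 10 of them in the cell cycle list, whose 19 tested members had positive values (median log2 3.40, camera adjusted p = 9.1e-35, adjusted p = 0.347 with an estimated correlation). Among those with counts in NK, chosen after their values were seen, were Prc1 (3.28 ± 0.38 SE), Ncapg2 (3.00 ± 0.37), Atad2 (2.56 ± 0.38) and Kif18a (2.24 ± 0.30), genes of mitosis or chromatin. Others were Egfem1 (2.32 ± 0.30), one of the fixed DCT2 markers, B4galnt2 (2.88 ± 0.35), Plet1 (2.52), Alcam (1.27) and the growth factor gene Nrg1 (1.24 ± 0.19). This class held RNA of the DCT, with Slc12a3 at 71.8 per 10000 UMIs, and its own RNA was not separated from it. The summed counts of connecting tubule or principal-like nuclei include cycling nuclei, on average 10.9% of the class in KD. The edgeR calls therefore need not mark a change across the class. Those outside the list also include further genes of cell division, such as Ttk and Melk. DESeq2 called 95 genes here, and 707 passed at an unadjusted p under 0.05. The count was 14 without NK replicate 3, 16 without NK replicate 2, 21 without KD replicate 2, 38 without KD replicate 3 and 173 without KD replicate 1.

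In thick ascending limb-like nuclei edgeR called 0 of 11762 genes (386 at an unadjusted p under 0.05, 11 with DESeq2), while all 12 cell cycle genes tested had positive values (median log2 1.67, camera adjusted p = 1.0e-18, adjusted p = 0.0625 with an estimated correlation, 0.0238 with fry). In proximal tubule-like nuclei it called 0 of 14895 (412 unadjusted, 9 with DESeq2), and all 16 cell cycle genes had positive values (median 1.03, adjusted p = 3.1e-19, adjusted p = 0.0201 with an estimated correlation). In intercalated-like nuclei it called 0 of 11402 (296 unadjusted, 0 with DESeq2), and the 4 cell cycle genes tested gave a median of 0.27 (adjusted p = 0.254, adjusted p = 0.667 with an estimated correlation). These classes also held RNA of the DCT, with Slc12a3 at 76.3 per 10000 UMIs in thick ascending limb-like, 2.58 to 72.6 in proximal tubule-like and 61.1 to 69.0 in intercalated-like clusters, against 69.6 to 185 in DCT-like clusters. Their own RNA was not separated from it, and the cholesterol synthesis, fatty acid oxidation, immediate early, oxidative phosphorylation, ribosomal and cell cycle lists were called in the same direction in DCT-like nuclei. Cholesterol synthesis genes were lower in KD in all 3 of these classes, with adjusted p = 9.9e-04, 4.7e-05 and 3.5e-05 for thick ascending limb-like, proximal tubule-like and intercalated-like nuclei, and adjusted p = 0.148, 0.266 and 0.532 with an estimated correlation. In connecting tubule or principal-like nuclei neither this list (adjusted p = 0.156) nor fatty acid oxidation (0.105) was called. Immediate early genes were higher in KD in intercalated-like nuclei (adjusted p = 2.6e-07, adjusted p = 0.538 with an estimated correlation) and in proximal tubule-like nuclei (adjusted p = 4.7e-05, adjusted p = 0.0805 with an estimated correlation). The same list was called upward in connecting tubule or principal-like (adjusted p = 0.0087, adjusted p = 0.471 with an estimated correlation) and thick ascending limb-like nuclei (adjusted p = 0.0035, adjusted p = 0.654 with an estimated correlation). Oxidative phosphorylation genes were called downward in connecting tubule or principal-like, thick ascending limb-like, intercalated-like and proximal tubule-like nuclei (adjusted p = 5.1e-06, 1.1e-05, 0.0206 and 0.0078), with adjusted p = 0.471, 0.654, 0.667 and 0.793 with an estimated correlation. Ribosomal protein genes were called downward in the last 3 of these (adjusted p = 1.1e-05, 9.4e-04 and 2.6e-05), with adjusted p = 0.654, 0.667 and 0.749 with an estimated correlation. Fatty acid oxidation genes were higher in thick ascending limb-like (adjusted p = 1.8e-05, adjusted p = 0.292 with an estimated correlation) and proximal tubule-like nuclei (adjusted p = 7.4e-06, adjusted p = 0.337 with an estimated correlation). Fatty acid oxidation genes were also higher in intercalated-like nuclei (adjusted p = 7.4e-04), as was the heat shock list (7.4e-04), both with adjusted p = 0.532 with an estimated correlation. Clock genes were called downward in thick ascending limb-like nuclei (adjusted p = 0.0378, adjusted p = 0.654 with an estimated correlation). Ankrd33b stood at 29.4 CPM in DCT-like nuclei of NK replicate 3 and at 1.16 to 1.82 in the other 5 libraries.

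Xist, the RNA that silences 1 X chromosome in female cells, stood at 1.24 CPM in KD replicate 2 and at 1233 to 1626 in the other 5 libraries, and Tsix, which overlaps it on the other strand, at 11.3 against 88.9 to 448. A male mouse was excluded by 0.166 CPM of 4 Y-linked genes in that library, below the 0.202 to 0.437 of the others. A pair of active X chromosomes would raise X-linked genes, but their median log2 against the other libraries was 0.00140 over 266 genes. Genes that escape silencing were lower in it, with a median log2 of −0.763 and 4 of 4 lowest in KD replicate 2, as a single X chromosome needs. A single X chromosome in this mouse is therefore a candidate explanation, and no biological explanation tied to the groups was tested.

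Nuclei of clusters not named DCT-like also carried Slc12a3 RNA, at 2.58 to 72.6 per 10000 UMIs over the proximal tubule-like clusters, 53.1 to 88.9 in the other named classes and 45.7 to 142 in the unnamed clusters, against 69.6 to 185 in the DCT-like clusters, with predicted doublets still counted. The unnamed cluster at 142 was led by Slc8a1, Ryr2, Calb1 and Trpv5, and 69.9% of its nuclei were predicted doublets. It therefore need not lie outside the DCT. The tests covered the proximal tubule-like clusters alone, with predicted doublets left out. Free RNA would reach these clusters alike, but in the library with the lowest ratio the cluster with the most Slc12a3 had 7.58 times that of the cluster with the least. A DCT nucleus captured together with a proximal tubule nucleus would bring its whole RNA, and the median UMI count of the cluster with the most over the sum of the medians of both kinds was 0.966 (SD 0.0317), so joint capture may account for the Slc12a3 RNA of that cluster, as a hypothesis found and tested on the same data. For the other classes no such test was run, and both intercalated-like clusters stood alike, at 61.1 and 69.0. In the single libraries the proximal tubule-like cluster with the least Slc12a3 held 1.07 to 8.34 per 10000 UMIs. That lies far below the 53.1 to 88.9 of the other named classes. Free RNA would reach all nuclei of a library, so these values argue against it as the main source in the other named classes, while joint capture stays open there.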
